A study of Arabidopsis thaliana with 3 samples.

How the data were processed

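RNA of inflorescence meristems and flower buds was analysed from 3 libraries, each of 1 independent transgenic line of the sep1 sep2 sep3 triple mutant expressing SEP3Δtet. The plants grew in parallel in long days, per the series text, and paired reads of 150 bp were obtained on an Illumina instrument by a service company. The 3 libraries form 1 group; libraries of the triple mutant alone are not among the samples used here. Reads were aligned with STAR, counted with featureCounts and compared with edgeR, on the TAIR10 genome, per the submitters' processing notes. Versions, the treatment of strand and of reads shared between genes, the filter on low counts, the number of control libraries and the model formula are not given in the sources used here. The series text calls the lines independent, and p-values measure the spread between the libraries of the authors' fit.

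The authors deposited 1 comparison table of 19777 genes. Its columns are, per the file headers, a log2 fold change, an average log2 CPM over all libraries of the fit, an F statistic (a score with no fixed range), a p-value and its adjusted p-value, the set that edgeR's quasi-likelihood F-test gives. Positive log2 fold changes are read as higher in the SEP3Δtet lines, from the order in which the authors name the 2 genotypes of the comparison. The table has no value per library and no standard error, so depth per library is unknown and no interval is given. The deposited adjusted p-values equal a Benjamini-Hochberg adjustment of the deposited p-values over all rows, to within 1.8e-15. A denominator of 11.85 degrees of freedom was recovered from F and p for 85.4% of the 13963 genes where it could be solved, within a tolerance of 0.02. Of the gene identifiers, 152 carry an isoform-like suffix, 7493 genes have a symbol in the table and 12284 have none. Locus identifiers were looked up in the TAIR10.1 annotation, where 19756 were found and 21 were not; coordinates are from that annotation and not from the table, whose build is TAIR10 per the submitters' processing notes. No plastid or mitochondrial gene is in the table.

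Calls are genes with a deposited adjusted p under 0.05, by the sign of the log2 fold change. A set of 16 gene lists (252 distinct genes, 222 in the table) was fixed before the data were examined: floral MADS homeotic genes, flowering time, meristem, carpel and ovule, anther and tapetum, mature pollen, meiosis, organ growth, photosynthesis, auxin and gibberellin, jasmonate, flavonoid, cutin, cell division, circadian clock and heat shock. Each list was tested for higher and for lower calls with a two-sided Fisher's exact test against all genes of the table, with Benjamini-Hochberg adjustment over the 32 tests, of which 10 passed (5 for higher and 5 for lower calls). SEP1, SEP2 and SEP3 were left out of these tests because they are mutated or added by design. The floral MADS homeotic list also holds AP2, which encodes no MADS protein. The median log2 fold change of each list was placed among 10000 random lists of the same size matched on deciles of average log2 CPM. Random lists describe the table; percentiles under 2.5 or over 97.5 are read as apart. Calls were also counted with p-values adjusted over the list alone.

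Genes named in the text were set by a rule fixed before the data were examined: SEP1, SEP2 and SEP3; the 10 largest increases and the 10 largest decreases among calls with an average log2 CPM of at least 1; and of each list up to 4 called members with the smallest p, plus AP3, PI, AG, AP1, SHP1, SHP2, CRC and WUS. This gave 71 genes, of which 38 are higher, 29 lower and 4 not called; the values of 1 of them are not reported here. Named outside that rule, after the results were seen, are AP2, SEP4, LFY, FD, SPL4, SPL9, CUC1 and CUC3. So are NGA1, NGA2, NGA3, STY1, STY2, HSP18.2, HSP70-1, VGD1 and PGA4. Genes named only in the part on other observations are outside the rule too. Gene functions are background knowledge. Families of at least 5 genes, made by removing the trailing number of the gene descriptions in the table, were tested in the same way after the table had been looked at, as were 8 added lists, the neighbouring gene window and the line of genes with almost no reads in the triple mutant.

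The planned spread between the 3 lines, the SEP3 level per line, the genes with the largest gap between lines, their versions under other normalizations and the fits without 1 line were not computed, because no values per library were used here. The code of the list tests was checked on simulated data made from the table's 19777 genes: over 50 tables with shuffled calls, 0 gave any called list, and a planted list of 20 genes with 12 made higher was recovered with all 12 at percentile 100. The planting fixed that recovery in advance, so it checks the code only. Shuffling breaks the links between genes, so the 0 does not cover lists of co-regulated genes. Alternatives tried were an adjusted p of 0.01, a log2 fold change of at least 1, genes with an average log2 CPM of at least 1 or 4, Bonferroni adjustment, unmatched random lists, recentring on abundant genes, and leaving out the anther, pollen and meiosis lists. For recentring, p-values were recomputed from the distance to the new centre and the spread that F implies, the absolute log2 fold change over the square root of F. That implied spread was also ranked for a gene among the 300 genes nearest in average log2 CPM, or in average log2 CPM and log2 fold change, and clock genes were set against random lists drawn from the 300 genes nearest to each in average log2 CPM and implied spread. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.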

Results

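Poly(A) RNA was sequenced from inflorescence meristems and flower buds of 3 independent transgenic lines of Arabidopsis thaliana, with 1 library per line. The plants were triple mutants for SEP1, SEP2 and SEP3 and expressed SEP3Δtet, which the series title describes as a splice variant of SEPALLATA3. SEP proteins are MADS-domain transcription factors that act with the other floral homeotic proteins to specify floral organs. The labels place the oldest buds at stages 10 to 11 in line 1, 10 to 12 in line 2 and 10 to 13 in line 3, while the series text gives stages 10 to 11 for all lines. The values analysed are those of the authors' comparison of these lines with the triple mutant, so the level in each line, the spread between lines and the depth of each library are unknown. In the authors' deposited table, the average abundance of the 19777 genes over all libraries of the fit ran from -1.83 to 12.54 log2 CPM, with a median of 4.46. The comparison asks which genes differ in RNA level when this SEP3 variant is expressed and no other SEP1, SEP2 or SEP3 function is present. In RNA of whole meristems and buds, control by the variant cannot be told apart from a changed share of organs or tissues. This limit holds for every list below.

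SEP3 itself, the gene of the transgene, was 4.82-fold higher in the transgenic lines in the authors' deposited table (log2 fold change 2.27, F = 88.7, adjusted p = 1.1e-04 by edgeR's quasi-likelihood test). SEP1 and SEP2, mutated in both genotypes, did not pass the test, with log2 fold changes of -0.59 (adjusted p = 0.288) and 0.67 (adjusted p = 0.678) in the authors' deposited table. The spread that F implies was wide for all 3 genes, at percentile 98.3 for SEP1, 100 for SEP2 and 97.3 for SEP3 among genes of like abundance, so a missed call of SEP1 or SEP2 does not show an equal level. SEP3 (AT1G24260) lies on chromosome 1 from 8593536 to 8596123 on the minus strand of the TAIR10.1 annotation, SEP2 (AT3G02310) on chromosome 3 from 464279 to 467151, and SEP1 (AT5G15800) on chromosome 5 from 5151334 to 5154253. In that annotation the full SEP3 transcript has 8 coding exons, and its isoform 3 has 7, lacking exon 6 (8594201 to 8594242, 42 bp, 14 codons). Transcripts of the transgene and of the mutant endogenous allele were not told apart by a value per gene.

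Genes of anther development and meiosis rose in the transgenic lines and genes of photosynthesis fell. Across the authors' deposited table, 2294 genes were higher and 1163 lower at an adjusted p of 0.05, together 17.5% of those tested. Increases were much larger than decreases: the higher calls had a median log2 fold change of 1.88 and the lower calls one of -0.45 in the authors' deposited table. A change of at least 2-fold was found for 1562 higher and 74 lower genes, and one of at least 8-fold for 737 higher and 0 lower genes. The excess of higher calls lay among less abundant genes: of 11025 genes between 4 and 8 log2 CPM 736 were higher and 852 lower in the authors' deposited table, and of 582 genes above 8 log2 CPM 24 and 98. At an unadjusted p of 0.05, 5870 genes passed. After recentring on abundant genes (average log2 CPM of at least 4, median -0.04), a setting chosen after the data were seen, 2510 genes were higher and 854 lower.

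Among genes with an average log2 CPM of at least 1, the largest increases in the authors' deposited table were those of AT1G27570 (log2 fold change 10.95), the oligopeptide transporter gene OPT9 (10.34), AT2G32460 (9.96, a myb domain gene) and AT2G42470 (9.67, TRAF-like). They were followed in the authors' deposited table by AT3G58290 (9.38, TRAF-like), the zinc finger gene AT3G46070 (9.37), the actin gene ACT12 (9.31), AT3G10116 (9.09), the kelch repeat gene AT2G22030 (8.93) and AT4G29250 (7.88). All but AT4G29250 belong to 114 genes whose log2 fold change exceeded their average log2 CPM by more than 7, the position of genes with almost no reads in the triple mutant. Fitted folds of these genes depend on the prior count and give no bound on the true change, and 97 of the 114 were called higher in the authors' deposited table. No gene held the mirror position on the lower side.

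Decreases were smaller. The largest in the authors' deposited table were those of AT2G43610, a chitinase family gene (log2 fold change -2.76), the morning clock gene LHY (-2.67), AT5G02580 (-2.09) and ESM1 (-2.08). AIR3 (-1.75), the beta-carotene hydroxylase gene AT5G52570 (-1.70) and the receptor-like protein gene RLP11 (-1.66) came next in the authors' deposited table. The expansin gene EXPA8 (-1.65), NF-YA10 (-1.64) and AT3G55240 (-1.59) complete the 10 in the authors' deposited table.

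**Figure D1:**
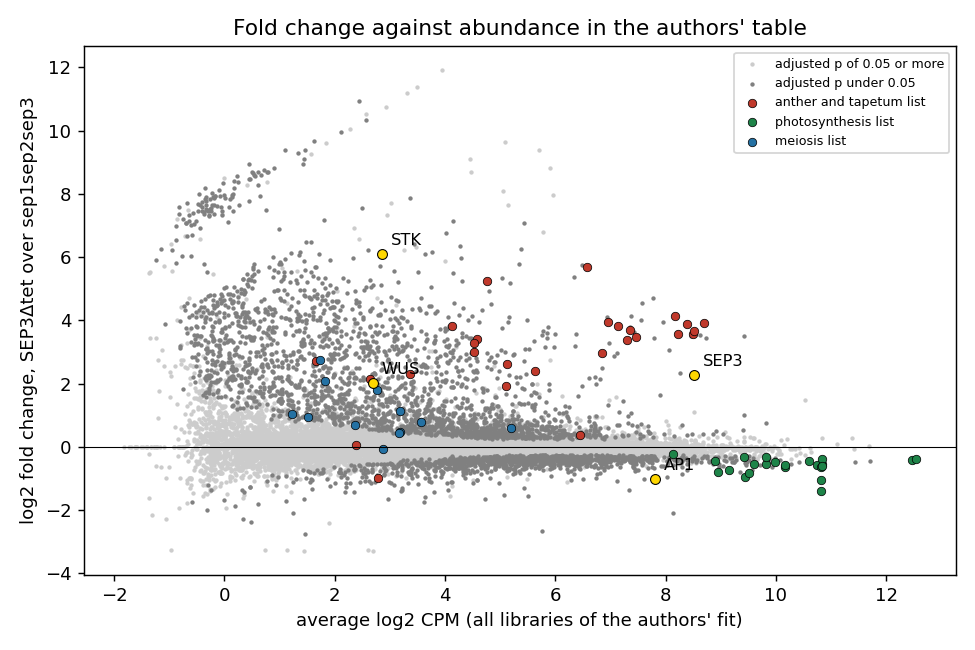
Log2 fold change of SEP3Δtet lines over the triple mutant (vertical axis) against average log2 CPM over all libraries of the authors' fit (horizontal axis), 1 point per gene of the authors' deposited table; dark points passed an adjusted p of 0.05, and coloured points are members of 3 gene lists or single named genes. Anther and tapetum genes lie far above 0, with a median of 3.42, and photosynthesis genes lie at high abundance below 0, with a median of -0.55.

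Genes of the floral MADS homeotic list moved in both directions. Of 15 measured, 6 rose, 3 fell and 6 were not called, and 9 were called when adjusted over the list alone. AP2, a member that is not a MADS gene, was among those that fell (log2 fold change -0.54 in the authors' deposited table). The lower calls of this list therefore include AP2. SEP4, a SEP gene that is not among the 3 mutated ones, also fell (-0.71 in the authors' deposited table). Besides SEP3, STK, which acts in ovule identity, rose in the authors' deposited table (log2 fold change 6.09, adjusted p = 4.6e-04), as did the carpel and fruit genes SHP2 (2.58, adjusted p = 0.0032) and SHP1 (1.53, adjusted p = 7.2e-05). PI, a petal and stamen identity gene, rose by 0.77 (adjusted p = 0.0017) in the authors' deposited table, and its partner AP3 by 0.33 (adjusted p = 0.047), a call lost when only genes of at least 1 log2 CPM are adjusted (0.050). AP1, a sepal, petal and floral meristem identity gene, fell 2.004-fold (F = 147, adjusted p = 5.7e-06) in the authors' deposited table. AG, which specifies stamens and carpels, stood at 0.16 (adjusted p = 0.440) in the authors' deposited table. With SEP1, SEP2 and SEP3 left out, 5 of 12 genes were higher (Fisher's exact test, adjusted p = 0.029) and 3 lower (adjusted p = 0.087). The median log2 fold change of those 12 was 0.15, at percentile 98.1 of random lists matched on abundance.

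Flowering-time and inflorescence identity genes included 3 that rose, 5 that fell and 7 not called, of 15 measured, with 9 called when adjusted over the list alone. The floral repressor genes FLC (log2 fold change 3.57) and TEM2 (3.54) rose in the authors' deposited table, as did the floral integrator SOC1 (0.66). SPL5, which promotes the floral transition, fell in the authors' deposited table (-0.92, adjusted p = 0.0013). LFY (-0.73), FD (-0.54), SPL9 (-0.42) and SPL4 (-0.41) fell as well in the authors' deposited table. SPL4, SPL5 and SPL9 are also in the SPL family tested among the other observations, so the 2 results overlap. Lower calls were enriched (Fisher's exact test, adjusted p = 0.0082), although the list's median (0.05) and mean (0.51) were positive.

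Of 16 meristem and determinacy genes, 2 rose, 4 fell and 10 were not called, with 7 called when adjusted over the list alone. WUS, which maintains the stem cell population, rose in the authors' deposited table (log2 fold change 2.01, adjusted p = 2.5e-04). CLV1, whose receptor kinase restricts WUS, fell there (-0.66 in the authors' deposited table), as did PNF (-0.49) and KNAT1 (-0.35). Lower calls were enriched (Fisher's exact test, adjusted p = 0.039) but not after recentring, where 2 genes stayed lower (adjusted p = 0.343), and the median of -0.08 and the mean of 0.14 differ in sign.

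Carpel, ovule and fruit genes split: of 22 measured, 8 rose, 5 fell and 9 were not called, with 13 called when adjusted over the list alone. SPL/NZZ, needed for both anther and ovule sporogenesis, rose in the authors' deposited table (log2 fold change 2.69, adjusted p = 3.2e-07), as did NGA4 (2.73) and VDD (2.65), a target of the ovule MADS proteins. The 5 that fell in the authors' deposited table were NGA1 (-0.75), NGA2 (-0.81), NGA3 (-0.78), STY1 (-0.82) and STY2 (-0.48), so the NGA genes did not move together. CRC, a carpel and nectary gene, was not called in the authors' deposited table (0.24, adjusted p = 0.495). Both higher calls (adjusted p = 0.0105) and lower calls (adjusted p = 0.029) were enriched by Fisher's exact test, and the median of 0.23 lay at percentile 96.9 of matched lists. STK, SHP1 and SHP2 stand in this list and in the MADS list.

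Anther and tapetum genes rose together: 24 of 27 measured were higher, 1 was lower and 2 were not called, and 26 were called when adjusted over the list alone. The tapetum regulators AMS (log2 fold change 3.47, adjusted p = 2.8e-07), MYB80 (3.82, adjusted p = 7.9e-07) and BHLH89 (2.63, adjusted p = 5.0e-07) rose in the authors' deposited table. TKPR1, an enzyme of sporopollenin synthesis, rose in step (3.58, adjusted p = 2.8e-07 in the authors' deposited table). The list's median was 3.42, at percentile 100 of matched lists, and higher calls were enriched (Fisher's exact test, adjusted p = 1.0e-18). AMS (AT2G16910) lies on chromosome 2 from 7331721 to 7334254 in TAIR10.1. None of 7 measured mature pollen genes was called by edgeR's test, also when adjusted over the list alone (0), and 2 had an unadjusted p under 0.05. Those 2, VGD1 (log2 fold change 7.48) and PGA4 (4.23), averaged -0.66 and -0.47 log2 CPM in the authors' deposited table. The lack of calls therefore does not show that pollen transcripts stayed level. The median of the 7 was 0.49, at percentile 80.8, and 7 more were not in the table.

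Meiosis genes rose as well, 8 of 12, with 0 lower and 4 not called; 10 were called when adjusted over the list alone. MMD1 (log2 fold change 2.73), the cohesin gene SYN1 (2.07), the chromosome axis gene ASY1 (1.80) and the recombinase gene DMC1 (0.60) rose in the authors' deposited table. Their median of 0.86 lay at percentile 99.7 of matched lists, and higher calls were enriched (Fisher's exact test, adjusted p = 1.1e-04).

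**Figure D2:**
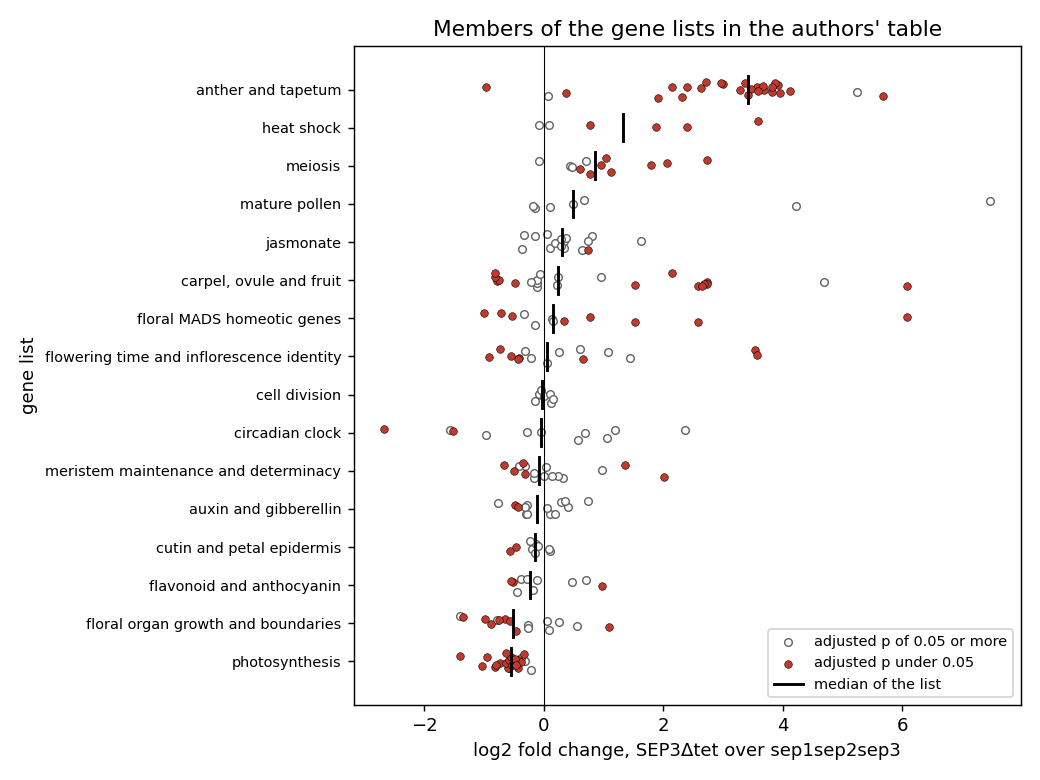
Log2 fold change of SEP3Δtet lines over the triple mutant (horizontal axis) for the measured members of 16 gene lists (vertical axis) in the authors' deposited table; filled points passed an adjusted p of 0.05, open points did not, bars are list medians, and SEP1, SEP2 and SEP3 are not drawn. Medians run from -0.55 for photosynthesis to 3.42 for anther and tapetum.

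Photosynthesis genes fell: 20 of 23 were lower, 0 higher and 3 not called, and 22 were called when adjusted over the list alone. The light-harvesting genes LHCB1.1 (log2 fold change -1.40), LHCB1.2 (-1.04), LHCA4 (-0.63) and LHCA2 (-0.55) fell in the authors' deposited table. The list's median was -0.55, at percentile 0 of matched lists, and lower calls were enriched (Fisher's exact test, adjusted p = 1.0e-20). The values of LHCB1.1 and LHCB1.2, nearly identical copies, are uncertain because the treatment of reads shared between genes is not given in the sources used here.

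Among floral organ growth and boundary genes, 7 of 16 fell, 1 rose and 8 were not called, with 10 called when adjusted over the list alone. JAG, a promoter of organ growth, fell in the authors' deposited table (log2 fold change -0.89, adjusted p = 7.0e-04), as did TCP4 (-0.74) and BOP2 (-0.47). The boundary gene CUC2 rose in the authors' deposited table (1.09, adjusted p = 3.5e-04). CUC3 fell there (-0.65) and CUC1 was not called (-0.27 in the authors' deposited table), so the CUC genes did not move together. The median of -0.51 lay at percentile 0 of matched lists, and lower calls were enriched (Fisher's exact test, adjusted p = 1.4e-04).

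Few hormone genes were called. Of 14 auxin and gibberellin genes, 2 fell, 0 rose and 12 were not called, with 2 called when adjusted over the list alone. ARF8, an auxin response factor gene, was among those that fell in the authors' deposited table (log2 fold change -0.42, adjusted p = 0.039). Lower calls were not enriched (Fisher's exact test, adjusted p = 0.395), the median was -0.11, and 1 gene stayed lower after recentring. In the jasmonate list MYC2 was the 1 gene of 16 to rise in the authors' deposited table (0.75, adjusted p = 0.019), 15 were not called, and 1 was called when adjusted over the list alone. Higher calls were not enriched (Fisher's exact test, adjusted p = 1), although the list's median of 0.31 lay at percentile 100 of matched lists.

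In the flavonoid list of 10 measured genes, 1 rose, 2 fell and 7 were not called, with 3 called when adjusted over the list alone. F3'H rose (log2 fold change 0.98) while FLS1 (-0.55) and CHI (-0.52) fell in the authors' deposited table, with a list median of -0.23 at percentile 1.18 and no enrichment of lower calls (Fisher's exact test, adjusted p = 0.260). After recentring, 0 flavonoid genes were lower. The cutin and petal epidermis list held 2 genes that fell and 7 not called of 9, with 2 called when adjusted over the list alone, a median of -0.14 and no enrichment (Fisher's exact test, adjusted p = 0.250). Those were the epidermal regulator MYB16 (-0.56), also in the organ growth list, and the wax gene CER1 (-0.46) in the authors' deposited table. None of 8 cell division genes was called by edgeR's test, also when adjusted over the list alone (0), and 0 had an unadjusted p under 0.05; their median of -0.02 and mean of 0.009 differ in sign. After recentring that median is 0.02.

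Both morning regulators of the clock fell, and 4 of 6 measured heat shock genes rose. CCA1 (log2 fold change -1.51, adjusted p = 0.039) and LHY (-2.67, adjusted p = 0.040), MYB-related repressors of evening genes, fell in the authors' deposited table, while 0 of the 11 clock genes rose (1 after recentring) and 9 were not called. When adjusted over the list alone 4 were called, the median was -0.05, and lower calls were not enriched (Fisher's exact test, adjusted p = 0.285). Of 6 heat shock genes 4 rose, 0 fell and 2 were not called, with 4 called when adjusted over the list alone. The 2 not called were HSP18.2 (log2 fold change -0.08) and HSP70-1 (0.09) in the authors' deposited table, and 4 more genes of the list were not measured. HSFA2 (3.59), HSP90-1 (2.39), DREB2A (1.87) and HSP101 (0.77), which act in heat and stress responses, rose in the authors' deposited table. The list's median of 1.32 lay at percentile 99.7 of matched lists, and higher calls were enriched (Fisher's exact test, adjusted p = 0.0105).

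Genes of a list are not independent replicates, so the list tests describe this comparison and not further plants. Whether all 3 lines carried each change is not known from one value per gene.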

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

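Recentring, the setting restricted to genes of at least 4 log2 CPM, and leaving out the anther, pollen and meiosis genes were chosen after the data were seen. Over the whole table, higher calls exceeded lower ones in these settings: 1482 and 419 at an adjusted p of 0.01, 481 and 14 by Bonferroni, 1562 and 74 with a log2 fold change of at least 1, 1720 and 1098 at 1 log2 CPM or more, 2510 and 854 recentred, and 2262 and 1162 without the anther, pollen and meiosis genes. Genes of 4 to 8 log2 CPM showed the reverse, 736 and 852. Of 32 list tests, 29 kept their side of the threshold at an adjusted p of 0.01, where MADS lower calls passed (0.0082) and lower calls of meristem (0.663) and carpel genes (0.251) did not. With a log2 fold change of at least 1, 26 kept it: MADS higher (0.224), organ growth lower (0.224) and flowering, meristem and carpel lower calls (1 each) were lost, and clock lower calls passed (0.0079). At 4 log2 CPM or more 26 kept it, and MADS higher (0.285), meristem lower (0.144), carpel higher (1) and lower (0.713), meiosis higher (0.233) and heat shock higher calls (0.0785) were lost, with fewer genes tested. Recentred, 30 kept it, with MADS lower calls passing (0.0434) and meristem lower calls lost (0.343). A background of at least 1 log2 CPM moved 0 of 32. The causes of the other changes were not tested. Anther higher and photosynthesis lower calls passed in all of these list settings. With a log2 fold change of at least 1, however, the photosynthesis lower calls were LHCB1.1 (-1.40) and LHCB1.2 (-1.04) alone in the authors' deposited table. These are the nearly identical copies whose values are uncertain. Of 71 named genes, 57 stayed on their side at an adjusted p of 0.01 and 23 by Bonferroni, where SEP3 reached 0.0583. Unmatched random lists left 13 of 16 lists on their side of the percentile bounds, with MADS at 92.8, carpel at 99.7 and mature pollen at 98.96. No paired analysis was possible because the labels give 1 group and no values per library were used here. Alternatives for the spread between lines, the SEP3 level per line and the fits without 1 line were not run for the same reason. Low depth cannot be told from low expression in this table.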

Other observations

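The families, the gene window, the added lists and all tests in this part except the one on the second set of dawn and dusk genes matched on abundance were chosen after the results were seen. Of 678 families tested in both directions, 20 were enriched for higher and 7 for lower calls at an adjusted p of 0.05 (Fisher's exact test). Among genes described as F-box and associated interaction domains, 30 of 50 were higher in the authors' deposited table (adjusted p = 7.6e-13), with a median log2 fold change of 3.17, and so were 36 of 85 kelch repeat genes (adjusted p = 7.7e-10). SKP1-like genes, whose products link F-box proteins to cullin, rose in 8 of 11 cases in the authors' deposited table (adjusted p = 5.2e-04), among them ASK5 (log2 fold change 4.29), ASK13 (3.91) and ASK14 (5.07). Further families with higher calls in the authors' deposited table were DUF577 (10 of 12), ubiquitin carboxyl-terminal hydrolase-related (10 of 13), TRAF-like (10 of 24), lipid-transfer (19 of 46) and myb domain proteins (23 of 63). Recentring left each of these counts as it was. Members of such families can share reads, which makes their single values uncertain. Kelch genes cluster: of 15 neighbouring genes in the table from AT2G29720 to AT2G29940, 10 were higher in the authors' deposited table, 7 of them kelch repeat genes, and 7 of 1000 shuffles of the calls held a window with as many.

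Lower calls were enriched among leucine-rich receptor-like kinase genes (11 of 22, adjusted p = 9.4e-06 by Fisher's exact test), including CLV1 (log2 fold change -0.66), BAM2 (-0.46) and BAM3 (-0.32) in the authors' deposited table. The larger family described as leucine-rich repeat protein kinases was not enriched (11 of 84 lower, adjusted p = 0.363 by Fisher's exact test). Growth-regulating factor genes, which promote cell proliferation in organs, were lower in 6 of 9 cases (adjusted p = 5.2e-04), with GRF5 at -0.60 and GRF3 at -0.49 in the authors' deposited table. Of 14 measured SPL transcription factor genes, 10 share 1 description and were tested as a family, of which 6 were lower (adjusted p = 9.2e-04), led by SPL5 (-0.92) and SPL10 (-0.66) in the authors' deposited table. After recentring, 8, 5 and 4 genes of these families stayed lower.

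The sign of the fold change of clock genes went with the time of day at which they peak, but few were called. In the authors' deposited table, 6 of 6 dawn genes of the clock list were negative and 2 called lower, with a median log2 fold change of -1.24. The dusk genes were positive in 5 of 5 cases and 0 were called higher, with a median of 1.07. Clock genes also had a wide implied spread, at a median percentile of 98.7 among genes of like abundance. Against random lists matched on abundance and implied spread the dawn genes lay at percentile 0 and the dusk genes at 71.4, but those lists lean upwards (95% of their medians from -0.14 to 2.61 and from -0.20 to 3.499), so neither value decides on chance shifts. A candidate explanation is collection of the genotypes at different hours: in a second set not looked at before, 5 of 7 dawn genes were negative and 2 called lower (median -0.60, percentile 0.01), and 7 of 7 dusk genes were positive and 2 called higher (median 1.67, percentile 99.99) against lists matched on abundance alone. Matched on implied spread too, the second sets lay at percentiles 0.01 and 61.9, with random medians that again lean upwards (-0.20 to 1.79 and -0.03 to 4.12). The hour and an effect of SEP3Δtet on the clock both stay open, since no hour of collection is given in the sources used here and genes of 1 rhythm are not independent.

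Photosynthesis genes were lower, with a median log2 fold change of -0.55 in the authors' deposited table. A lower signal of all abundant genes is argued against by the 582 genes above 8 log2 CPM, whose median was -0.06. The list also lay at percentile 0 among lists matched on deciles of abundance, but the top decile includes many genes less abundant than these. A trend among the most abundant genes alone was not tested. Dilution of all other transcripts by added anther RNA stays open. The cell division list had a median of -0.0215 (95% bootstrap interval over genes -0.08 to 0.12) against -0.62 to -0.43 for photosynthesis. Added anther RNA can itself hold cell division transcripts, so that list cannot decide. Other lists differed, with medians of -0.51 for organ growth and -0.14 for cutin and petal epidermis. Collection at different hours cannot be told apart from a change of genotype, because no hour is given in the sources used here and both kinds of photosynthesis gene moved: 14 of 14 light-harvesting genes were lower, with a median of -0.60, and 6 of 9 others, with a median of -0.38. A lower share of green tissue in the transgenic flowers stays open as untested.

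Late anther genes had large folds but few calls. Of 12, all were positive in the authors' deposited table with a median log2 fold change of 5.68, and 4 were called, against 9 of 9 early anther genes with a median of 2.69. The early genes were chosen after the results were seen. Among the anther and tapetum genes left out were ROXY1 (-0.97, called lower), TPD1 (0.08, not called) and EMS1 (0.38, called higher) in the authors' deposited table. The 9 of 9 and the median of 2.69 therefore depend on that choice. Spread was also ranked among the genes nearest in abundance and fold. QRT3, MS1, GRP18 and EXL5, with log2 fold changes of 2.98 to 3.91, lay at percentiles 83.3 to 98.7. Early genes, with 2.14 to 3.82, lay at 4.3 to 64.3. At like abundance and fold, however, a wider implied spread only restates a smaller F. These 4 late genes were also picked after the results were seen, so the ranks do not decide. Low counts and large folds alone stay open as an explanation for all 12 late genes. The median of all late genes was 98.2, but their nearest genes had smaller folds (4.34, the median over late genes of the mean of their nearest genes). Whether that raises the percentile was not tested. Libraries that differ in how far the anthers had developed stay open as well: the implied spread of the late genes lay 12.3 percentile points above that of the early genes (two-sided exact permutation test over genes, p = 8.6e-04), but large folds with few calls already mean a wide spread, so this decides nothing. The labels give a different oldest stage for each line but the series text gives 1 stage range for all, and which libraries differ was not seen.

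For the SPL genes, more miR156 activity is a hypothesis that stays open, since miR156 targets part of that family. The 8 measured genes with a miR156 site had a mean log2 fold change of -0.48 ± 0.25 (SD over genes) and the 6 without one -0.15 ± 0.14 in the authors' deposited table, a difference of -0.33 (two-sided exact permutation test over genes, p = 0.0093). All 8 with a site were negative and 6 of them called lower, against 4 negative and 0 called of the 6 without one. The test was made because 6 genes of the family were already known to be lower, so its p largely restates that count, and no small RNA was analysed here.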
